A study of Drosophila melanogaster with 4 samples.

How the data were processed

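Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on Drosophila melanogaster embryos aged 8 to 16 h of a line that carries a GFP-tagged genomic copy of Hr78. Hr78 is an orphan nuclear receptor, a DNA-binding transcription factor of the hormone receptor family. Per the labels' protocols, embryos were crosslinked in 1.8% formaldehyde for 15 min and chromatin was precipitated with a rabbit polyclonal antibody against GFP. The series holds 4 libraries, 2 of GFP ChIP DNA and 2 of input DNA, and samples were grouped by their titles. Nothing in the labels says whether the libraries of a group came from separate embryo collections.

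The authors deposited 1 peak list for the whole series. It gives the start, the end and a score for each of 1524 peaks, and per the file headers its positions refer to FlyBase release 5 of the genome. Its source column names MACS, a peak caller that compares ChIP coverage with a background. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5. The score is the authors' value for each peak, as deposited, and its scale is not named in the file. The threshold for calling a peak, the handling of reads that map to several places, and the way in which the 2 ChIP and 2 input libraries were combined are not given in the sources used here. Values per library were not analysed here, so no peak has a replicate error, and the sequencing depth is unknown. All tests below are therefore across peaks of a single list, peaks are not independent replicates, and intervals and p-values cover counting error or chance placement only.

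No reference genome of release 5 was used here. The gene table at hand belongs to release 6, whose coordinates differ, so no peak was assigned to a gene. The planned analyses of transcription start sites, genomic classes, divergent promoters, 24 gene lists, 28 sequence motifs and the Hr78 locus were left out for that reason. Peaks are named by position, 1-based, on release 5. The rule for naming them was fixed before the data were examined: the 20 peaks with the highest score, ties going to the wider peak, and the highest peak of each arm. Groups and windows of peaks that are named besides these were chosen after their values were seen.

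Comparisons used the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4 as the main set. The length of an arm was taken as its span from the first to the last peak, as planned for the case that no release 5 sequence was at hand. Spans were taken anew for each set of peaks, so they can be shorter where fewer peaks are kept. A span is shorter than its arm, and not by the same amount on each arm. The first peak of X starts at 531066, while those of the other large arms start between 18250 and 73524. Counts of peaks per arm were tested against the share of each arm in the summed span with two-sided exact binomial tests, adjusted over the 6 arms by the Benjamini-Hochberg method. In the alternative that kept all sequences with at least 2 peaks, the summed span and the adjustment covered all of these sequences. Rates per Mb carry exact Poisson 95% intervals, and ratios of rates carry exact conditional intervals. Distances between midpoints of neighbouring peaks were compared with 1000 random placements of the peaks within the span of their own arm, which give a smallest p of 0.001. Width and score were correlated across peaks, with 100000 permutations and a smallest p of 1e-05. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

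The statistics were tested on simulated data. With 1095 simulated peaks and a density on 4 that was 4 times that of the other arms, the arm test called 4 in 100 of 100 lists with a mean estimated ratio of 4.04. With no excess it called 4 in 0 of 100 lists, although the mean estimated ratio was 1.19, since the span is underestimated where peaks are few. The spacing test called 20 of 20 lists with added neighbours and 0 of 20 uniform lists. In the lists with added neighbours, a mean of 44.5% of peaks had a neighbour within 5 kb, more than the 31.1% observed below. Lists without an effect held independent positions, so they give no error rate for peaks that lie in groups. Alternatives fixed beforehand were the arm peaks at or above their median score (548 of 1095), called higher-scoring peaks below, all sequences with at least 2 peaks, peaks under 100 bp apart merged, a neighbour distance of 10 kb and chromosome 4 left out. Alternatives added after the data were seen were groups of peaks with at most 5 kb from the end of one peak to the start of the next counted once, a dense stretch of 2L left out, placement within 500 kb of each peak, and only those peaks whose score lay on the steps of a common background.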

Results

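The binding of GFP-tagged Hr78 to chromatin of embryos aged 8 to 16 h was profiled in 2 ChIP libraries against 2 input libraries, and the design asks where in the genome ChIP signal exceeds input. The authors' list holds 1524 peaks on 15 sequences of release 5, which together cover 652409 bp. Peaks were narrow, with a median width of 377.5 bp, an interquartile range of 273 to 516 bp and a full range of 201 to 1797 bp. The median score was 21.0, with an interquartile range of 13.2 to 39.6 and a range from 6.49 to 397.1. No value has a replicate error, since the list is common to all libraries.

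Of the 1524 peaks, 1095 lay on the chromosome arms, which is 71.9% of the list (exact 95% binomial interval 69.5 to 74.1%). The unplaced sequences U and Uextra, which collect contigs with no assigned position and are rich in repeats, held 379 peaks or 24.9% (22.7 to 27.1%). The heterochromatin scaffolds of chromosomes 2, 3, X and Y held 38 peaks, and the mitochondrial genome held 12. The median score was 18.6 on the arms, 26.4 on unplaced sequence, 42.9 on the heterochromatin scaffolds and 38.4 on the mitochondrial genome. The median width was 401 bp on the arms and 328 bp on unplaced sequence.

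The 7 highest scores of the list, from 346.3 to 397.1, all belonged to peaks on unplaced sequence, 568 to 815 bp wide. The first was at Uextra 27103591 to 27104192 and the second, with a score of 387.4, at Uextra 6118267 to 6118866. The next were Uextra 23790152 to 23790943 at 378.9, Uextra 2831291 to 2831886 at 369.4, U 9538403 to 9538970 at 368.3, Uextra 13798631 to 13799240 at 365.2 and Uextra 21748087 to 21748901 at 346.3. Ranks 11, 12, 15 and 20 were also on Uextra, at 14829705 to 14830205, 19622129 to 19622639, 7039350 to 7039801 and 28493058 to 28493520, with scores of 234.5, 223.3, 214.1 and 167.3. In all, 11 of the 20 highest peaks were on unplaced sequence, 1 was on a heterochromatin scaffold (3LHet 1396326 to 1397202, score 215.6) and 8 were on the arms.

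The highest peak on an arm, rank 8 of the list, was at 2R 15993786 to 15994373 with a score of 255.3. Chromosome arm 3L followed with 3L 6118012 to 6118699 at 239.2 and 3L 4402901 to 4403880 at 235.4. The highest peak of X was at X 5930888 to 5931992, 1105 bp wide, with a score of 214.1. On 2L it was 2L 5000974 to 5001949 with a score of 198.8, which stood in a group of 4 peaks between 4997267 and 5004562. Arm 3R had 3 peaks among the 20 highest, at 15686906 to 15687484, 8889459 to 8890430 and 8537921 to 8538736, with scores of 193.8, 188.1 and 183.6. The highest peak of chromosome 4, at 4 1202172 to 1202942, scored 114.8 and ranked 47 in the list.

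**Figure D1:**
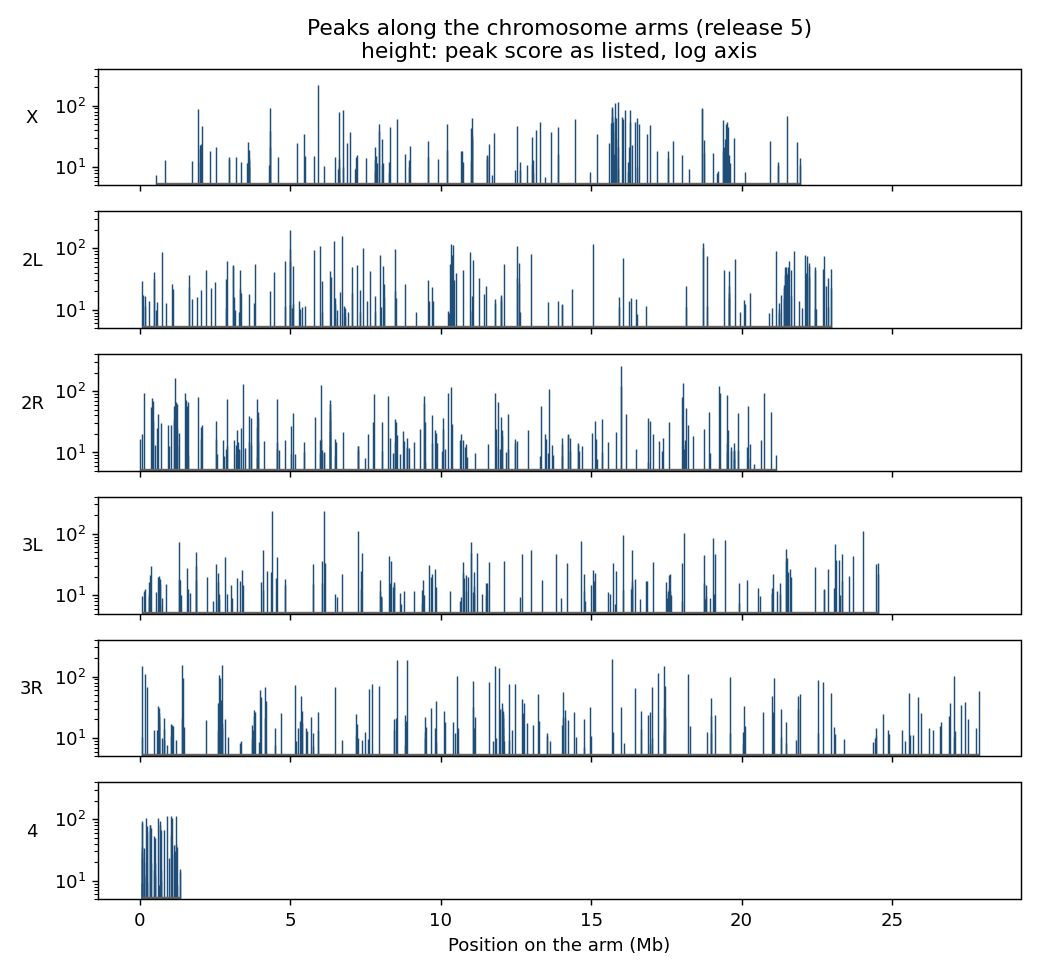
Peaks along the 6 chromosome arms, one panel per arm, with the position in Mb on the horizontal axis and the score of each peak on a logarithmic vertical axis. The grey bar marks the span from the first to the last peak; chromosome 4 is short and densely filled, and 2R holds the highest peak, with a score of 255.3.

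The next comparison asked whether peaks are spread over the arms in proportion to length. Chromosome 4, the small and mostly heterochromatin-like dot chromosome, stood apart with 47 peaks in 1.28 Mb, or 36.6 peaks per Mb (95% interval 26.9 to 48.7). The 5 large arms together had 1048 peaks in 117.7 Mb, or 8.90 per Mb. The density on 4 was 4.11 times that of the other arms (3.00 to 5.51), and 47 peaks stood against 11.8 expected from length (exact binomial test, adjusted p = 3.2e-14). Scores were also higher there, with a median of 35.4 on 4 against 17.9 on the other arms (two-sided permutation test, p = 0.00018). Peaks on 4 were wider, with a median of 536 bp against 394.5 bp (two-sided permutation test, p = 0.00026). The comparisons of score and width on 4 were added after the data were seen. Width and score are related across peaks, as given below, so these comparisons are not independent of each other.

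Among the large arms, 2R was the densest, with 235 peaks or 11.1 per Mb (9.75 to 12.6), which is 1.21 times its expected count (exact binomial test, adjusted p = 0.0053). Arm 2L had 9.13 peaks per Mb (7.93 to 10.5), 0.99 times expected (exact binomial test, adjusted p = 0.94). Of its 209 peaks, 27 lay in a single stretch described below, and the remaining 182 peaks came to 7.95 per Mb. Arms 3L, with 207 peaks and 8.46 per Mb (7.35 to 9.70), and 3R, with 229 peaks and 8.23 per Mb (7.20 to 9.37), did not pass the threshold (exact binomial tests, adjusted p = 0.23 and 0.081). Arm 3L passed with a deficit among the higher-scoring peaks, at 0.76 times expected (exact binomial test, adjusted p = 0.011, against 0.13 to 0.51 in the other alternatives). Arm 3R passed with all sequences kept, at 0.88, and with only the peaks on the score steps described at the end, at 0.83 (exact binomial tests, adjusted p = 0.043 and 0.025, against 0.15 to 0.78 in the other alternatives). The excess on 2R did not pass among the 548 peaks at or above the median score of the arms, where its ratio was 1.13 (exact binomial test, adjusted p = 0.26, against 0.0013 to 0.032 in the other alternatives), and the ratio of 2L, which did not pass in any set, was 1.10 there. Peaks lie in groups, so these tests, which treat each peak as independent, give p-values that are too small.

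**Figure D2:**
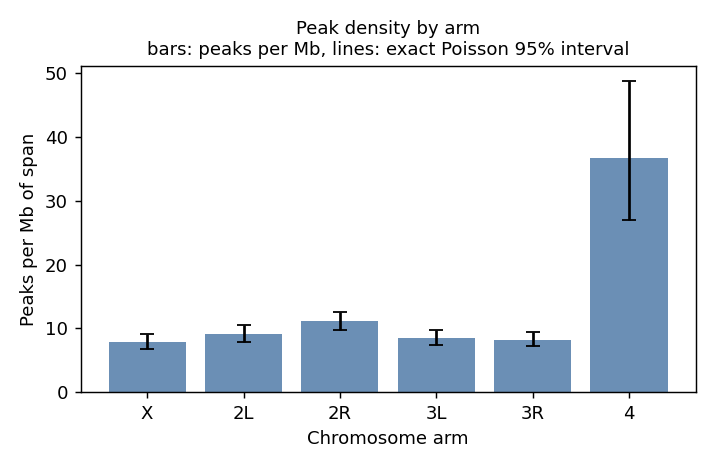
Peaks per Mb of span for each chromosome arm, as bars from 0 with exact Poisson 95% intervals as lines. Chromosome 4, at 36.6 peaks per Mb, lies above the 5 large arms, which range from 7.85 on X to 11.1 on 2R.

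The X chromosome had the lowest density, with 168 peaks or 7.85 per Mb (6.71 to 9.13). These were 15.3% of the arm peaks (13.3 to 17.6%), against 17.98% expected from its span, a ratio of 0.85 (two-sided exact binomial test, p = 0.022 against the autosomes and 0.045 adjusted over the 6 arms). The span of X begins at its first peak, at 531066, further into the arm than on the other large arms. Its expected share may therefore be too low, which affects all ratios for X. Such a bias would make these ratios too high, and a deficit would look smaller than it is. Against the autosomes, the deficit did not pass the threshold with chromosome 4 left out (ratio 0.88, exact binomial p = 0.072), among the higher-scoring peaks (0.87, p = 0.17) or without the dense stretch of 2L (0.87, p = 0.056). With 5 kb groups counted once (0.84), it passed against the autosomes (exact binomial p = 0.026). It did not pass there when adjusted over the 6 arms (exact binomial test, adjusted p = 0.051). When only the peaks on the score steps described at the end were counted, the ratio was 1.05 (exact binomial p = 0.47), a change that follows from the higher share of X peaks on the steps, 92.3% against 74.9% of all arm peaks.

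Peaks were grouped along the arms. Of the 1095 arm peaks, 340 (31.1%) had another peak within 5 kb, measured between midpoints, against a median of 9.50% in random placements (95% of placements between 7.21 and 12.0%; permutation test, p = 0.001, the smallest that 1000 placements can give). The median distance between neighbours was 45866.5 bp, against 72734 bp in random placements. With at most 5 kb from the end of a peak to the start of the next, which joins slightly more peaks than midpoints do, the peaks formed 886 groups, of which 738 were single peaks, 119 were pairs and 29 held 3 or more peaks. Those 29 groups comprised 8 on 2R, 6 on 3L, 5 each on X and 2L, 3 on chromosome 4 and 2 on 3R. Examples are a group of 6 peaks at 2R 6305487 to 6317915 with a highest score of 71.4, a group of 5 at 2R 1578273 to 1589640 with 65.6, a group of 4 at X 6617519 to 6628035 with 78.1 and a group of 4 at 4 76832 to 88328 with 88.4. A group of 5 at 3L 626864 to 635357 and a group of 4 at 3L 8013643 to 8016712 had lower highest scores, of 20.3 and 9.56. When peaks were placed at random within 500 kb of their own position, which keeps the regional density, 11.1% had a neighbour within 5 kb, still below the observed 31.1%.

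The stretch with the most peaks lay on 2L between 21419669 and 21542380, a length of 122.7 kb with 27 peaks, or 12.9% of all peaks of that arm. To find it, groups of 5 or more peaks that lay under 20 kb apart were joined, here groups of 7 and 20 peaks. Some shorter groups had more peaks per kb. Its peaks were of moderate height, with a median score of 25.2 and a range from 9.36 to 50.0, and a median width of 483 bp. They followed each other at even steps: 19 of the 26 distances between neighbouring midpoints were within 10% of the median of 4.97 kb, with a standard deviation of 150 bp among the 19, and 17 of these steps were consecutive. The grouping of peaks along the arms held without this stretch, with 29.96% of peaks having a neighbour within 5 kb against 9.27% in random placements (permutation test, p = 0.001, the smallest possible).

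**Figure D3:**
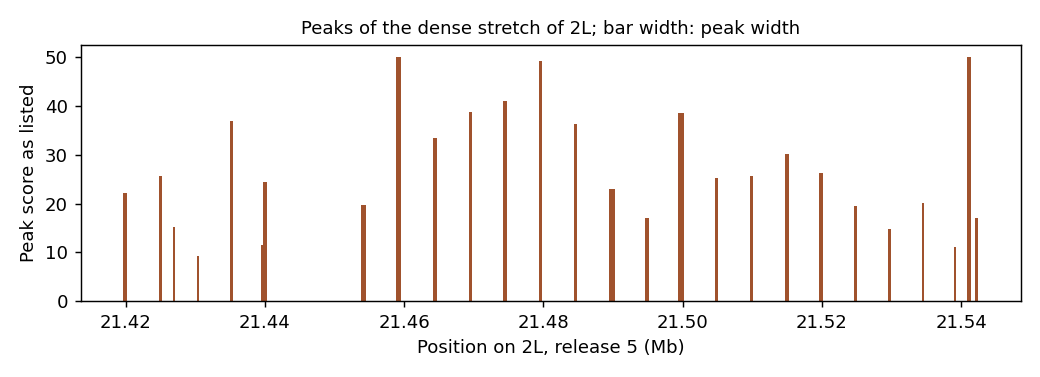
The 27 peaks of the dense stretch of 2L between 21419669 and 21542380, with the position in Mb on the horizontal axis and the score on the vertical axis. Each bar spans the width of its peak, and most neighbours stand about 4.97 kb apart.

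Wider peaks had higher scores. Across the 1524 peaks, Spearman's rho of width and score was 0.60 and Pearson's r was 0.44 (two-sided permutation tests, each p = 1e-05, the smallest possible, before and after adjustment over the 10 sets of peaks compared). The relation held within every arm, with rho between 0.67 on X and 0.73 on 2R, and was lower on unplaced sequence, with rho of 0.45. Leaving out the 2 peaks whose width was farthest from the median left r at 0.44. These correlations are across peaks of a single list. Width and score come from the same peak calling, so their relation may follow from the calling itself, which was not tested.

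The scores took only 735 different values. For 964 of the 1524 peaks (63.3%), the score lay within 0.015 of a step of −log10 of the upper tail of a Poisson distribution with a mean of 48.94, a mean fitted to the scores themselves. The share on these steps was 92.3% on X and 93.6% on chromosome 4. On 2L, 2R, 3L and 3R it was 66.0, 73.6, 72.5 and 69.9%. It was 29.6% on unplaced sequence, and 2 of the 12 mitochondrial peaks, all 7 of the highest unplaced peaks and 2 of the 27 peaks of the dense stretch of 2L were on the steps.

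**Figure D4:**
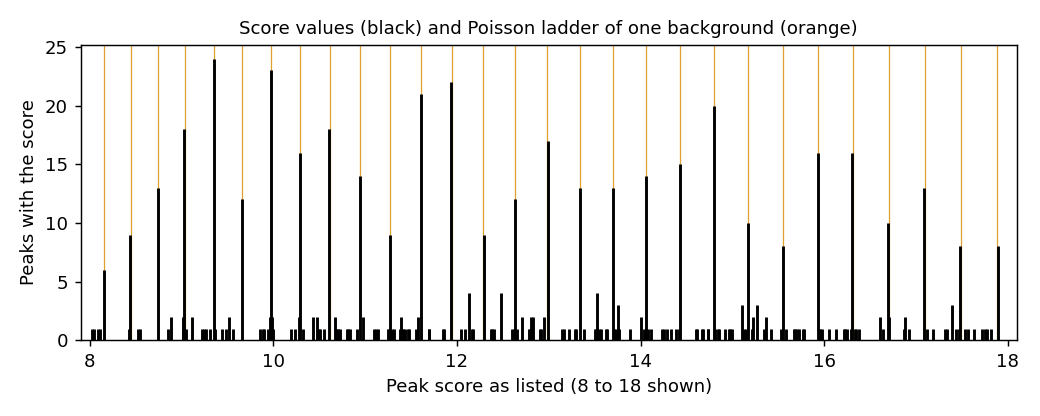
Number of peaks (vertical axis) with each score value between 8 and 18 (horizontal axis, black), with the steps of −log10 of the upper Poisson tail for a mean of 48.94 in orange. The most frequent values, such as 24 peaks with a score of 9.35, stand on the steps.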

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

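The comparisons between arms leave out 3 kinds of sequence in which peaks were nonetheless listed, and these were set apart for that reason. The test of their scores against those on the arms was chosen after the data were seen. Unplaced sequence held 379 peaks, among them the 7 highest scores of the list, and 29.6% of its scores lay on the steps of the common background, against 74.9% on the arms (Fisher's exact test, two-sided, p = 5.6e-55). The heterochromatin scaffolds held 38 peaks, of which 30 were on the steps. The mitochondrial genome held 12 peaks, with scores between 9.90 and 105.0; the 4 peaks between 17573 and 19238 included the highest at 18848 to 19238. No level in control samples was at hand for these sequences, and no explanation was tested for them.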

How the results depend on the processing

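Of 62 recomputed values of 11 results with a test, 49 kept their direction and their side of the threshold. X enters both among the 6 arms and against the autosomes, with the same ratios, so the results are not independent. Values that passed in neither setting also count as kept. Peak number, median width and median score, which have no test, became 1498, 384 bp and 21.4 with peaks merged. The excess on chromosome 4 kept both under all 6 alternatives run for it, with ratios to the expected count from 3.24 to 6.20. The grouping of peaks and the relation of width to score also kept both under each alternative run for them. For grouping, the alternative with all sequences kept is of limited use. It includes distances on U and Uextra, whose contigs have no assigned position. The ratio for X among the 6 arms lost its call among the higher-scoring peaks (0.87), with 5 kb groups counted once (0.84) and without the dense stretch of 2L (0.87), and reversed among peaks on the score steps (1.05). Against the autosomes, the ratio for X lost its call among the higher-scoring peaks (0.87), without the stretch (0.87) and with chromosome 4 left out (0.88), and reversed on the steps (1.05). Among the higher-scoring peaks, 2R lost its call (1.13), 3L gained a deficit (0.76) and 2L, without a call in any setting, reversed (1.10). Arm 3R gained a deficit with all sequences kept (0.88, against 0.89 in the main set) and on the score steps (0.83). With all sequences kept, the ratios of all 6 arms were slightly lower, since the other sequences enter the expected counts. The call on 3R there is therefore not a change particular to that arm. The ratios on the score steps follow from the share of each arm's peaks that is on them. The higher-scoring peaks are 548 in place of 1095, and a cut by score moves the ratio of an arm by its own scores. Median scores were 21.9 on 2L, 16.7 on 2R and 16.3 on 3L, against 18.6 on all arms. The ratio of 2L among higher-scoring peaks without its dense stretch was not computed, and otherwise the cause was not tested. The settings of 5 kb groups, the left-out stretch, the score steps and placement within 500 kb were chosen after seeing the data. No paired analysis was possible because the values are common to all libraries, so no replicate could be left out either. Alternatives on start sites, gene classes, gene lists and motifs, and the share of genes as an expectation, were not run, since no release 5 annotation was used here; the span as an expectation is the main setting. The unknown depth limits all values: no peak can be called absent.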

Other observations

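Chosen after the data were seen were the tests on the repeated score values, the even spacing in the 2L stretch, coverage of X, the centromere ends, the densest windows, and weak peaks and local background on chromosome 4. The set of higher-scoring peaks was fixed beforehand and its use for weak peaks on 4 was not, and the 5 kb groups were added after the data were seen, with their test on 4 laid down before its result. The X chromosome held a cluster of high peaks. A window of 445.7 kb at X 15597787 to 16043465 held 18 peaks, against a median of 10 and a maximum of 16 for the densest 500 kb window in 1000 random placements (permutation test, p adjusted over 6 arms = 0.006). These were strong peaks, with a median score of 57.2 against 16.7 on the rest of X and a highest score of 116.3, and all 18 were on the score steps. On 2R, a window at 1138513 to 1589640 held 19 peaks with a median score of 25.1 (permutation test, adjusted p = 0.006). The densest windows of 3L, at 291808 to 749208 with 16 peaks, and of 3R, at 601103 to 1089986 with 15 peaks, had lower median scores of 13.4 and 16.3 (permutation tests, adjusted p = 0.012 and 0.019). With its dense stretch left out, the densest window of 2L did not pass, nor did that of chromosome 4 (permutation tests, adjusted p = 0.23 and 0.34). Random placement treats each peak as independent, although peaks lie in groups, so these p-values are too small. Groups lay in the windows of 3L (5 peaks at 626864 to 635357), 2R (5 at 1578273 to 1589640) and X (3 at 15877461 to 15886360). Windows with such groups counted once were not tested.

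Peaks were denser towards the centromere on some arms. Within 2 Mb of the centromere end of the span, and without the dense stretch of 2L, there were 17 peaks per Mb on 2R against 10.5 on the rest of the arm, 14.5 against 7.32 on 2L and 13.5 against 7.82 on 3R. On 3L there were 8 per Mb against 8.51, and on X 4 against 8.25. Over the 5 large arms the ratio was 1.35 (95% interval 1.10 to 1.65, exact binomial test, p = 0.0034), and 1.67 with the stretch included. The direction was thus not shared by X and 3L. Of the 34 peaks in the centromere end of 2R, 19 lay in the densest window of that arm given above. On 3R it was 15 of 27. The excess on 2R and 3R, and the ratio over the 5 large arms, are therefore not separate from those windows, and the ratio without them was not computed. The p-value treats grouped peaks as independent and is too small.

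The repeated score values may be explained by a score that is −log10 of a Poisson p-value over a common background, which is a hypothesis about the authors' values. With the background fitted on every second peak, 62.3% of the 762 other scores lay within 0.015 of a step, against a median of 6.96% and a maximum of 9.71% when the scores were shifted at random in 1000 draws. Under this hypothesis, a peak on the steps has a height that can be read off, and the arm peaks on the steps range from 1.78 to 9.05 times the background, with a median of 2.51. The median would be 3.31 on chromosome 4 and 2.49 on the large arms, and the 7 highest unplaced peaks would stand at 10.9 to 11.9 times. The steps are 1 count apart, or 0.020 in these ratios. This spacing is not the error of a height, which was not computed. Some scores lie on a step by chance, as 6.96% of the shifted scores did. A score off the steps would then mark a peak tested against a local background above the common one.

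On chromosome 4, regions split into several peaks at most 5 kb apart account for no more than part of the excess of peaks. With 5 kb groups counted once there were 31 on 4, against 47 peaks. The ratio of densities was then 3.32 (95% interval 2.24 to 4.76), against 4.11 for peaks. Wider regions split into peaks more than 5 kb apart were not tested. Weak peaks near the threshold do not account for the excess, since the ratio among the higher-scoring peaks was 6.54 (4.48 to 9.26). Its direction was already given by the higher median score on 4. The 34 higher-scoring peaks on 4 span less of it than all its peaks do, which raises this ratio. Under the hypothesis on the score given above, a local background raised on 4 would put fewer of its scores on the steps. In the data, 93.6% of them were there against 74.0% on the other arms (Fisher's exact test, p = 0.0016). The scale of the score is not named, so this reading holds under that hypothesis only. A raised local background would also make a peak harder to call under it, so the share does not decide what the excess comes from. Gene density, mappability and base composition of chromosome 4 were not tested, and no biological explanation was tested.

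The even spacing in the dense stretch of 2L may reflect a tandem repeat with a peak in most copies. The 73.1% of its distances that lay within 10% of their median are the observation that prompted this hypothesis, so they are no independent test of it, and it stays open. A raised local background was tested on the scores, under the hypothesis on the score given above. Of the scores in the stretch, 7.41% were on the steps (95% interval 0.91 to 24.3%), against 74.7% on the rest of 2L (Fisher's exact test, p = 1.4e-11). A raised local background would also make a peak harder to call under that hypothesis. The share therefore does not decide why peaks are dense here, and it does not tell a raised background apart from a tandem repeat. The histone gene repeats are a well-known tandem array of this arm, and whether the stretch is that array was not checked, as no release 5 annotation was used here. Whether the peaks mark binding of Hr78 stays open too.

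The lower count on X may come in part from lower coverage of this chromosome, since males carry a single X and the labels name no sorting of embryos by sex. A caller that takes the higher of a common and a local background would then test most X peaks against the common one. In the data, 92.3% of the X scores were on the steps, against 70.6% on 2L, 2R, 3L and 3R (95% intervals 87.1 to 95.8% and 67.4 to 73.6%; Fisher's exact test, p = 1.9e-10). The share was as high on chromosome 4, an autosome, at 93.6%, so it does not set X apart from all autosomes and does not decide the question. Coverage itself was not measured here, and lower coverage and a difference in binding between X and autosomes both stay open.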
